A study of Mus musculus with 12 samples.

How the data were processed

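Gene expression was measured in pre-B cells sorted from the bone marrow of 12 mice, with 1 Affymetrix mouse expression array per mouse. The groups were normal wild-type mice, preleukemic mice and leukemic mice carrying the P190 BCR/ABL transgene, and leukemic transgenic mice treated with nilotinib, with 3 mice in each. Each mouse was processed separately, per the labels, and replicates were not pooled. The submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarizes probes into probe sets, without a version. The deposited table gives 1 intensity per probe set and array on a linear scale, from 2.98 to 22975, and log2 of these intensities was taken here. Background and detection values were not used here.

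The table held 45101 probe sets. Of these, 64 control probe sets were left out, 34945 named exactly 1 gene, 932 named several and 9160 named none. For each of the 18193 genes, the probe set with the highest mean over the 12 arrays stood for the gene. Gene names came from the table's own annotation, and 34741 of the probe sets had a gene identifier in the RefSeq table of GRCm38.p6, which was used for names alone. No genome build is named for the table, so no coordinates are given. The median intensity of an array lay between 43.6 and 49.7, and the number of arrays per group limits the precision.

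Group means were fitted to all 12 arrays in limma 3.58.1 under R 4.3.3, with no covariate and with the spread shared between the 4 groups and moderated across genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18193 genes. There were 5 comparisons: preleukemic with normal, leukemic with normal, leukemic with preleukemic, nilotinib with leukemic and nilotinib with normal. Tests were two-sided. A moderated F test covered the 4 groups at once. Changes in 2 comparisons with no shared array, preleukemic minus normal and nilotinib minus leukemic, were correlated across genes, which are not independent replicates, so no p is given. For comparisons that share arrays, shared calls were counted and the covariance of the changes was set beside that of unchanged groups in 20 simulations.

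The 29 gene lists, the tests, the comparisons and most alternatives were fixed before the data were examined. Lists of the B lineage were pro-B and pre-B cell genes, immature and mature B cell genes, and B-lineage transcription factors. Lists of signaling and stress were STAT5 target genes, MAPK and ERK feedback genes, FoxO target genes, NF-kappaB target genes, immediate early genes, interferon response genes, unfolded protein and ATF4 response genes, p53 target genes and BCL2 family genes. Lists of growth and metabolism were S phase and DNA replication genes, G2 and mitosis genes, ribosome biogenesis and MYC-linked genes, glycolysis genes, oxidative phosphorylation genes and cholesterol biosynthesis genes. The surface lists were sialylation and galectin genes, and adhesion and homing receptor genes. Marker lists covered granulocytes, monocytes and macrophages, erythroid cells, T and NK cells, plasma cells, stem and progenitor cells, megakaryocytes and platelets, stromal and endothelial cells, and sex-linked genes. None of the lists was drawn from these arrays. Some genes stand on more than 1 list.

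Each list was tested against all other genes with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 29 lists of a comparison. Camera with a correlation estimated for each list, and fry, which tests whether a list's genes move on balance one way, were alternatives. Named genes followed a rule. They were the 10 largest rises and 10 largest falls among called genes whose 3 arrays of one group all lay above the 3 of the other, and up to 4 called members of each list. Where no member was called, up to 2 members with the smallest p are given as values. Cd19, Cd93, Bcr and Abl1 were included whatever their result. Genes named outside this rule are marked as chosen after their values were seen.

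The procedure was tested on simulated data in which 200 of 18193 genes were changed, 100 by 2-fold and 100 by 4-fold, at the spread of these arrays. For leukemic with normal, 52% of the genes changed by 2-fold and 87% of those changed by 4-fold were recovered, with 5 false calls. For preleukemic with normal these shares were 69% and 92%, with 4 false calls. For leukemic with preleukemic they were 66% and 93%, with 5 false calls, for nilotinib with leukemic 58% and 92%, with 11, and for nilotinib with normal 68% and 87%, with 17. Each comparison had a single simulation with its own random genes, independent noise and the same spread in all groups. The shares therefore do not rank the comparisons. Arrays of unequal quality and correlated genes were not simulated.

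The alternatives tried were array medians set equal, a further quantile normalization, cyclic loess, a filter on dim probe sets, the mean of all probe sets of a gene, every probe set tested by itself, a spread with trend and robust fit, array weights (statmod 1.5.0), a fit to the groups of the comparison alone, the replicate number as a block, the log2 value of Xist as a covariate, the sex-linked genes left out, and each array left out in turn. Leaving out preleukemic replicate 3 in comparisons without preleukemic arrays, or both it and normal replicate 2, was added after the arrays were seen. Plots and array summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.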

Results

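The sorted cells carried CD19, a surface protein of the B lineage, and AA4.1, the product of Cd93, which marks early B-lineage cells. Normal cells came from wild-type C57BL/6J mice. The other 3 groups carried the P190 form of human BCR/ABL, a constitutively active tyrosine kinase that drives precursor B-cell acute lymphoblastic leukemia. Preleukemic mice were younger than 60 days and leukemic mice older than 90 days. The nilotinib group was leukemic mice given 75 mg/kg nilotinib, an inhibitor of the ABL kinase, for 7 days. Each group held 3 mice and each mouse 1 array. The values below are log2 of the deposited intensities, given as mean and SD. Means under the lower quartile of the arrays (an intensity of 11.21 to 12.57) are near the floor, so changes to or from them are given as levels and their size is not exact.

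Cd93 stood at 12.86 ± 0.11 in normal and 12.79 ± 0.14 in leukemic cells (SD, n = 3 each), with a log2 difference of -0.07 (SE 0.11) that did not pass the limma test (adjusted p = 0.717).
It was 12.89 ± 0.09 in preleukemic and 12.67 ± 0.03 in nilotinib cells. No probe set named Cd19 alone, so Cd19 was not measured here. Markers of other cell types varied between arrays. The mean of the monocyte and macrophage markers lay between 8.23 and 8.70 in normal arrays, at 8.32, 8.05 and 6.76 in preleukemic arrays, between 4.66 and 5.26 in leukemic arrays and between 8.93 and 10.61 in nilotinib arrays. The mean of the granulocyte markers was 6.00 in normal replicate 3 and 8.58 and 8.80 in the other normal arrays. It was 4.79 in preleukemic replicate 3 and 8.66 and 8.77 in the others of its group, 5.65 to 6.74 in leukemic arrays and 9.01 to 10.31 in nilotinib arrays. On a scale from the normal mean (0) to the leukemic mean (1) over genes called between these groups, preleukemic arrays stood at 0.20, 0.15 and 0.70. Each placed on genes called without it, normal arrays stood at 0.10, 0.02 and 0.24 and leukemic arrays at 0.80, 0.89 and 1.01. Nilotinib arrays stood at 0.55, 0.63 and 0.69.

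The log2 difference between the 3' and 5' probe sets of Gapdh, which grows as RNA degrades, was 3.42 in normal replicate 2 and 0.73 to 1.42 in the other arrays. That of actin was 2.12 in normal replicate 2 and 0.56 to 0.98 elsewhere. Xist, the RNA of the inactive X chromosome in females, was 4.17 and 5.43 in leukemic replicates 2 and 3 and 4.89 in nilotinib replicate 3. In the other arrays it lay between 12.23 and 12.89. The labels do not give the sex of the mice.

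**Figure D1:**
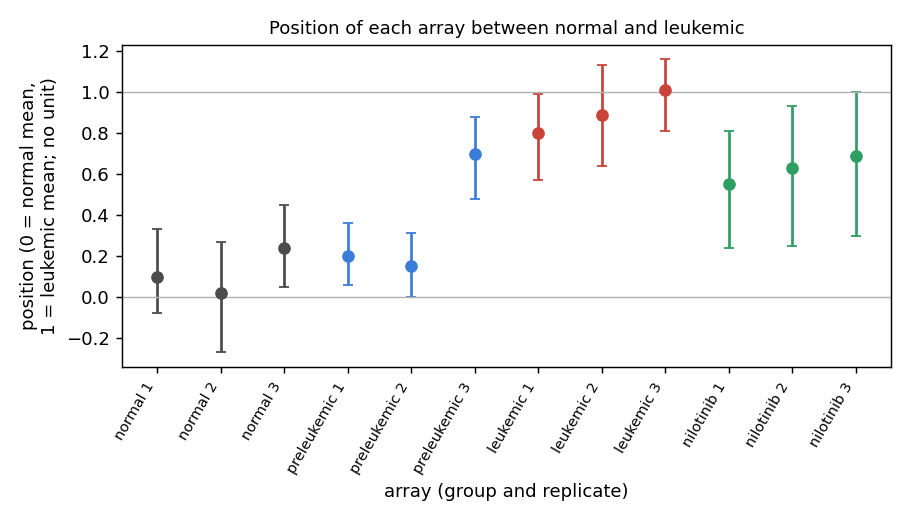
Position of each of the 12 arrays between the normal mean (0) and the leukemic mean (1), as the median over genes called between these groups, with bars for the interquartile range over genes. Normal and leukemic arrays were each placed on genes called without them. Preleukemic replicate 3, at 0.70, lies above the other preleukemic arrays, at 0.20 and 0.15.

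The comparison of preleukemic with normal cells asked what the transgene does before overt leukemia. In limma, 0 of the 18193 genes passed at an adjusted p under 0.05. Socs2, a feedback inhibitor of JAK and STAT signaling, was 12.03 ± 0.75 in preleukemic and 10.81 ± 0.60 in normal cells (SD, n = 3 each), a log2 difference of 1.21 (SE 0.36, adjusted p = 0.681). Etv5, an ETS transcription factor downstream of ERK, was 10.03 ± 0.78 and 8.53 ± 0.76 (SE of the difference 0.41), and Bcl2l2, a survival gene of the BCL2 family, differed by 1.83 (SE 0.36), with the same adjusted p. Bcl2l2 was the 1 gene to pass when adjusted over the list alone, in the list of BCL2 family genes. Asns, the gene of asparagine synthetase, was 9.04 ± 1.44 and 6.93 ± 1.07, and Fcer2a, the mature B cell antigen CD23, was 6.55 ± 2.08 and 8.17 ± 0.47, in preleukemic and normal cells.

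By list, the preleukemic median was lower than normal for 31 immature and mature B cell genes (-1.30 for Cr2, a complement receptor of mature B cells), with a list median of -0.66 and camera adjusted p = 0.00459. The same list had adjusted p = 0.923 with an estimated correlation. Its mean per array was 8.52 in preleukemic replicate 3 against 10.26 and 10.48 in the other preleukemic arrays. Monocyte and macrophage markers were also lower, with a median of -0.74 (adjusted p = 0.0174, and adjusted p = 0.923 with an estimated correlation). Genes of ribosome biogenesis (median 0.12, adjusted p = 0.00659), of the unfolded protein and ATF4 response (median 0.19, adjusted p = 0.00398), p53 targets (median 0.16, adjusted p = 0.00459) and MAPK and ERK feedback genes (median 0.16, adjusted p = 0.0243) were higher. With an estimated correlation these 4 had an adjusted p = 0.923 for the first and second and an adjusted p = 0.893 for the others. No member of any of the 6 lists was called, over all genes or adjusted over the list alone. The other 23 lists did not pass, with adjusted p from 0.053 for pro-B and pre-B cell genes upward.

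Beside the 0 calls of limma, 1312 genes had an unadjusted p under 0.05, 599 of them higher in preleukemic cells, and the smallest adjusted p was 0.551. In 2425 genes, 13.3%, all 3 preleukemic arrays lay on one side of the 3 normal arrays, and chance gives 10%. Without preleukemic replicate 3 the camera adjusted p was 0.795 for immature and mature B cell genes and 0.789 for ribosome biogenesis genes. It was 0.314 for unfolded protein and ATF4 response genes and 0.676 for macrophage markers. The B cell list then turned to higher only relative to all other genes. Its own means were 10.26 and 10.48 in the remaining preleukemic arrays and 10.70, 10.34 and 10.25 in normal arrays. The MAPK and ERK feedback list ended without normal replicate 1, 2 or 3 (adjusted p = 0.135, 0.0886 and 0.0546) and with the filter on dim probe sets (0.295), and the p53 target list without normal replicate 3 (adjusted p = 0.0546). Without normal replicate 1 the adjusted p was 0.219 for immature and mature B cell genes and for ribosome biogenesis genes and 0.145 for macrophage markers, which also ended without normal replicate 3 (0.147). Without normal replicate 2 it was 0.195 for ribosome biogenesis, which also ended with the filter (0.0826), and 0.0837 for the unfolded protein response.

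The comparison of leukemic with normal cells asked how overt leukemia differs from wild-type cells of the same sort gate. Leukemic cells had higher levels of 1582 genes and lower levels of 1622. Targets and feedback genes of kinase signaling were among the rises. Socs2 rose 4.90-fold (SE 0.36 on the log2 scale), Cish, another inhibitor of STAT5 signaling, 7.63-fold (SE 0.53), Myc 6.16-fold (SE 0.46) and Lif, a cytokine of the IL-6 family, 20.2-fold (SE 0.66), with n = 3 per group. Tead1, a transcription factor of the Hippo pathway, rose from 2.99 ± 0.52 to 9.35 ± 1.00 (adjusted p = 0.00304). Rbm24, an RNA-binding protein gene, fell from 10.27 ± 0.23 to 2.98 ± 0.23 (adjusted p = 0.00305). The lower levels of both lie near the floor. Fam117a fell from 9.68 ± 0.20 to 3.03 ± 0.23, and Cd163, a scavenger receptor of macrophages, fell from 8.86 ± 0.42 to 2.94 ± 0.34, levels near the floor in leukemic cells for both.

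Of 31 immature and mature B cell genes measured, 12 fell, 0 rose and 19 did not pass, and 15 were lower when adjusted over the list alone. H2-Aa, an MHC class II gene, fell 21.2-fold (SE 0.77, adjusted p = 0.00647). The list had a median log2 change of -1.63 and adjusted p = 3.2e-08 in camera, and adjusted p = 0.454 with an estimated correlation. Antigen presentation genes are also expressed by macrophages, whose marker mean lay between 8.23 and 8.70 in normal arrays and between 4.66 and 5.26 in leukemic arrays. FoxO targets moved the same way, with 6 of 24 falling and 0 rising (9 lower when adjusted over the list alone; median -0.32, adjusted p = 7.3e-04, and adjusted p = 0.454 with an estimated correlation). Among them were Rag1, a subunit of the antigen receptor recombinase, which fell 2.26-fold (SE 0.17), and Bcl6, a germinal center repressor, which fell 6.72-fold (SE 0.42). Of 31 B-lineage transcription factors, 9 fell, including Bach2 1.96-fold (SE 0.17), 4 rose and 18 did not pass. Adjusted over the list alone, 14 were lower and 4 higher, with adjusted p = 0.00657 in camera and adjusted p = 0.454 with an estimated correlation. The 25 pro-B and pre-B cell genes were mixed, with 4 higher, 5 lower and 16 not passing (4 and 9 when adjusted over the list alone), and the list did not pass (adjusted p = 0.149). Kit, a receptor of early progenitors, fell from 5.55 ± 0.90 to 2.95 ± 0.15, near the floor, while Bst1, a surface antigen of early B cells, rose 2.40-fold (SE 0.22).

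Lists of signaling genes were split. STAT5 targets had 6 members higher, among them Socs2, Cish, Myc and Socs3 (8.64-fold, SE 0.52), 5 lower and 8 not passing. Within the list, adjusted over the list alone, 6 were higher and 6 lower, and the list did not pass (median -0.15, mean 0.08, camera direction up, adjusted p = 0.866). MAPK and ERK feedback genes had 8 of 23 higher, including Etv5 5.40-fold (SE 0.41) and Dusp7, a phosphatase of ERK, 4.90-fold (SE 0.40), and 5 lower, including Dusp2 4.16-fold (SE 0.28). Adjusted over the list alone these counts were 8 and 7, and the list did not pass (adjusted p = 0.242). NF-kappaB targets fell in 13 of 23 members and rose in 2, with 15 lower and 3 higher when adjusted over the list alone (median -1.19, adjusted p = 2.2e-05, and adjusted p = 0.454 with an estimated correlation). Nfkb2 and Relb, of the noncanonical arm, fell 3.43-fold (SE 0.30) and 4.07-fold (SE 0.35), and Ccl3, a chemokine also made by macrophages, fell from 7.88 ± 1.00 to 3.55 ± 0.75. Immediate early genes fell in 6 of 26 members and rose in 1 (8 and 1 when adjusted over the list alone), with adjusted p = 0.00107 and adjusted p = 0.472 with an estimated correlation. Klf4 was among the falls, by 11.6-fold (SE 0.57).

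Survival and stress lists also held members on both sides. Of 19 BCL2 family genes, 5 rose, including Bcl2 5.11-fold (SE 0.35) and Bcl2l2 6.18-fold (SE 0.36), and 3 fell. Adjusted over the list alone, 7 were higher and 5 lower (median -0.03, mean 0.36, camera direction up, adjusted p = 0.564). Of 25 p53 targets, 5 rose and 4 fell (7 and 4 when adjusted over the list alone), and the list did not pass (adjusted p = 0.135). Cdkn2a, the tumor suppressor locus of p16 and ARF, rose 8.86-fold (SE 0.64), a call that ended with Xist as a covariate (adjusted p = 0.0702). The unfolded protein and ATF4 response list had 6 of 34 members higher and 3 lower (12 and 4 when adjusted over the list alone; adjusted p = 0.00377, and adjusted p = 0.472 with an estimated correlation). Asns rose 16.4-fold (SE 0.69), and Dnajc3, a chaperone of the endoplasmic reticulum, 1.56-fold (SE 0.11). Interferon response genes rose in 3 and fell in 4 of 33 members (3 and 5 when adjusted over the list alone). Rsad2, an antiviral gene, fell 9.33-fold (SE 0.59), and Gbp2, a guanylate-binding protein, rose 3.49-fold (SE 0.36). That list was called lower (median -0.50, adjusted p = 0.0224, and adjusted p = 0.626 with an estimated correlation), and its mean was 9.77 in leukemic replicate 1 and 8.13 and 8.34 in the other leukemic arrays. Its call ended without leukemic replicate 2 (adjusted p = 0.386), leukemic replicate 3 (0.152) or normal replicate 3 (0.106). Leukemic replicates 2 and 3 were also the leukemic arrays with low Xist. Nilotinib replicate 3, where Xist was low too, had a list mean of 8.95, against 9.48 and 9.30 in the other nilotinib arrays. The list was not tested with Xist as a covariate.

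Ribosome biogenesis and MYC-linked genes rose in 19 of 33 members and fell in 0, with 26 higher when adjusted over the list alone (median 0.68, adjusted p = 1.6e-12, and adjusted p = 0.454 with an estimated correlation). Gnl3, a nucleolar GTPase, rose 2.40-fold (SE 0.21), and Nolc1, a nucleolar chaperone, 1.97-fold (SE 0.17). S phase and DNA replication genes rose in 9 of 36 members, as many as when adjusted over the list alone, and fell in 0 (adjusted p = 2.4e-04, and adjusted p = 0.488 with an estimated correlation). G2 and mitosis genes rose in 2 of 39 members (1 when adjusted over the list alone; adjusted p = 0.0328, and adjusted p = 0.627 with an estimated correlation). The mitosis call ended without any 1 of normal replicates 1 and 2, leukemic replicates 1 and 2 or preleukemic replicate 3 (adjusted p = 0.241, 0.157, 0.0743, 0.0655 and 0.0506) and with the filter on dim probe sets (0.0938). Cholesterol biosynthesis genes rose in 6 of 20 members (9 when adjusted over the list alone; adjusted p = 0.00234, and adjusted p = 0.454 with an estimated correlation). Glycolysis genes rose in 7 and fell in 2 of 23 members (8 and 3 when adjusted over the list alone; adjusted p = 0.0155, and adjusted p = 0.454 with an estimated correlation). Slc2a3, a glucose transporter, rose 3.24-fold (SE 0.23), and Pdk1, a kinase that inhibits pyruvate dehydrogenase, 3.01-fold (SE 0.26). Oxidative phosphorylation genes rose in 1 of 37 members (0 when adjusted over the list alone), with a median of 0.13, adjusted p = 0.00673 and adjusted p = 0.522 with an estimated correlation. The adjusted p of that list was 0.245 without normal replicate 2, the array with the large Gapdh difference.

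Adhesion and homing receptor genes fell in 10 and rose in 2 of 26 members (12 and 2 when adjusted over the list alone; adjusted p = 0.00233, and adjusted p = 0.454 with an estimated correlation). Vcam1, a ligand of integrin alpha 4 that macrophages and stroma express, fell 33.7-fold (SE 0.89), and Itga6, an integrin that binds laminin, 2.60-fold (SE 0.22). Sialylation and galectin genes fell in 7 and rose in 3 of 29 members (9 and 5 when adjusted over the list alone), and the list did not pass (adjusted p = 0.0534). Cmah, which makes N-glycolylneuraminic acid, fell 38.6-fold (SE 0.88), Cmas, which activates sialic acid, fell 1.87-fold (SE 0.12), and St6galnac3, a sialyltransferase, rose 9.70-fold (SE 0.55).

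Several marker lists of other cell types were called lower in leukemic arrays, and others did not pass. Monocyte and macrophage markers fell in 15 of 19 members and rose in 0 (18 lower when adjusted over the list alone; median -3.78, adjusted p = 1.6e-12, and adjusted p = 0.454 with an estimated correlation), including C1qc, a complement gene, 20.7-fold (SE 0.56). Granulocyte markers fell in 1 of 17 members, as many as when adjusted over the list alone (adjusted p = 0.00673, and adjusted p = 0.518 with an estimated correlation), a call that ended without normal replicate 1 (adjusted p = 0.068). Erythroid markers fell in 2 of 13 members and rose in 1, Car2, carbonic anhydrase, by 4.37-fold (SE 0.31). The counts were 5 and 1 when adjusted over the list alone (adjusted p = 0.00831, and adjusted p = 0.454 with an estimated correlation), and the call ended with the filter on dim probe sets (0.0532). Plasma cell markers fell in 3 of 13 members (Sdc1, syndecan, 7.89-fold, SE 0.46), megakaryocyte and platelet markers in 3 of 13 and stromal and endothelial markers in 3 of 19, with the same counts when adjusted over the list alone. These 3 marker lists had adjusted p = 0.0258, 0.0161 and 0.0224, and adjusted p = 0.472, 0.472 and 0.454 with an estimated correlation. The T and NK cell markers (4 of 23 lower, adjusted p = 0.135), stem and progenitor cell markers (1 of 16 lower, adjusted p = 0.0534) and sex-linked markers (0 of 5, median 0.98, adjusted p = 0.756) did not pass. The plasma cell call ended without normal replicate 1 (adjusted p = 0.0596), normal replicate 3 (0.105) or leukemic replicate 2 (0.136) or with the filter on dim probe sets (0.0532), and the stromal call without normal replicate 2 (0.0806) or leukemic replicate 2 (0.0655).

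The arrays of the groups did not overlap in 3184 of the 3204 called genes, and in 34.1% of all genes, where chance gives 10%. The count of called genes was 1642 without leukemic replicate 3, 2059 without normal replicate 1, 2094 without normal replicate 2 and 886 with Xist as a covariate. Of 109 called genes named by rule, 71 stayed called under all 19 alternatives. Bcr, the mouse counterpart of a part of the transgene, fell 1.74-fold (SE 0.17, adjusted p = 0.0117), and Abl1 did not pass (10.11 ± 0.20 in leukemic and 9.89 ± 0.29 in normal cells, adjusted p = 0.485).

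**Figure D2:**
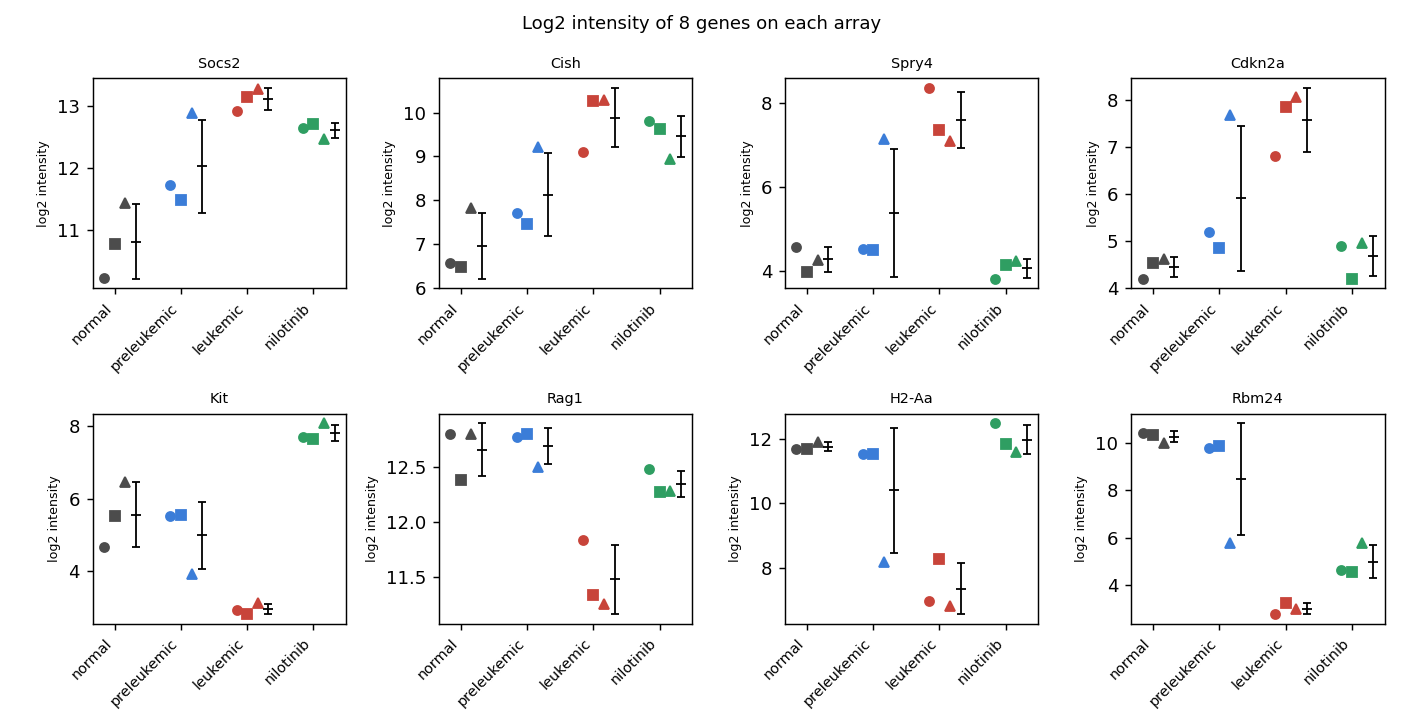
Log2 intensity of 8 genes on each of the 12 arrays, by group. Circles, squares and triangles are replicates 1, 2 and 3, and black marks give the mean and SD of 3 mice. Socs2 stands at 10.81 in normal and 13.11 in leukemic cells, and Rbm24 at 10.27 and 2.98.

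The comparison of leukemic with preleukemic cells asked what changes at the step to overt disease. Leukemic cells had 145 genes higher and 216 lower. Lrig3, a regulator of growth factor receptors, rose from 4.64 ± 0.15 to 7.89 ± 0.17 (SD, n = 3 each; SE of the log2 difference 0.24, adjusted p = 5.1e-04). Tubb3, a neuronal tubulin, rose 22.6-fold (SE 0.88), and Tnfsf11, the cytokine RANKL, 10.2-fold (SE 0.59). Rag1 fell 2.31-fold (SE 0.17), and Fabp4, a fatty acid binding protein of macrophages and fat cells, fell from 8.06 ± 0.86 to 3.31 ± 0.41, near the floor.

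In the B lineage, 2 of 25 pro-B and pre-B cell genes fell (8 when adjusted over the list alone), 3 of 31 B-lineage transcription factors fell (5), among them Bach2 1.76-fold (SE 0.17), and 3 of 24 FoxO targets fell (9), with no member of these lists higher. The list of 31 immature and mature B cell genes had 0 calls over all genes and 9 lower when adjusted over the list alone. These lists were called lower (adjusted p = 7.4e-04, 1.8e-04, 1.9e-07 and 1.9e-07), and had adjusted p = 0.185, 0.185, 0.166 and 0.381 with an estimated correlation. Monocyte and macrophage markers fell in 10 of 19 members (14 when adjusted over the list alone; median -2.69, adjusted p = 5.5e-16, and adjusted p = 0.185 with an estimated correlation). Their mean per array was 6.76 in preleukemic replicate 3, between those of the leukemic arrays and of the other preleukemic arrays. C1qc fell 12.9-fold (SE 0.56) and Cd163 from 8.01 ± 1.08 to 2.94 ± 0.34, near the floor.

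NF-kappaB targets fell in 2 of 23 members (13 lower and 2 higher when adjusted over the list alone), immediate early genes in 2 of 26 (5 and 1) and adhesion and homing receptor genes in 3 of 26 (8 and 2). Klf4 fell 9.76-fold (SE 0.57), and Cd9, a tetraspanin, 7.30-fold (SE 0.47). Sialylation and galectin genes fell in 2 of 29 members (3 lower and 1 higher when adjusted over the list alone), with St3gal5, the ganglioside GM3 synthase, down 3.06-fold (SE 0.32). The 4 lists had adjusted p = 1.9e-07, 2.7e-06, 1.4e-05 and 0.00257, and adjusted p = 0.198, 0.363, 0.185 and 0.185 with an estimated correlation. Ribosome biogenesis and MYC-linked genes rose in 1 of 33 members and in 25 when adjusted over the list alone (median 0.57, adjusted p = 7.7e-14, and adjusted p = 0.198 with an estimated correlation). S phase genes rose in 1 of 36 members (2 when adjusted over the list alone) and G2 and mitosis genes in 1 of 39 (1), with adjusted p = 1.4e-04 and 0.00238, and adjusted p = 0.467 and 0.577 with an estimated correlation. The mitosis call ended without preleukemic replicate 3 (adjusted p = 0.14). Cholesterol biosynthesis genes, glycolysis genes and oxidative phosphorylation genes were called higher as lists (adjusted p = 9.6e-04, 0.0277 and 0.0199, and adjusted p = 0.32, 0.386 and 0.621 with an estimated correlation), with 0 members called and 2, 3 and 0 higher when adjusted over the list alone. STAT5 targets (adjusted p = 0.566), MAPK and ERK feedback genes (median -0.03, mean 0.04, direction down, 0.883), p53 targets (median 0.11, mean 0.08, direction down, 0.895) and BCL2 family genes (0.956), and the unfolded protein and ATF4 response (0.182), stem and progenitor (0.0672) and sex-linked lists (0.773), did not pass.

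Interferon response genes fell in 1 of 33 members, as many as when adjusted over the list alone (median -0.53, adjusted p = 9.1e-06, and adjusted p = 0.386 with an estimated correlation), and the list mean was 9.77 in leukemic replicate 1 and 8.13 and 8.34 in the other leukemic arrays. The latter were the leukemic arrays with low Xist. Markers of erythroid cells (2 of 13 lower), T and NK cells (1 of 23), plasma cells (0 of 13), granulocytes (0 of 17), megakaryocytes (0 of 13) and stroma (1 of 19) were called lower as lists. They had adjusted p = 6.8e-04, 7.8e-04, 0.00286, 9.6e-04, 0.017 and 0.0403, and adjusted p = 0.32, 0.185, 0.363, 0.467, 0.386 and 0.386 with an estimated correlation. Adjusted over the list alone, 2, 2, 1, 0, 0 and 1 were lower. Alternatives ended some of these calls, the granulocyte call without preleukemic replicate 1 (adjusted p = 0.0542), the megakaryocyte call without preleukemic replicate 1 (0.0896) or leukemic replicate 1 (0.0534), the glycolysis call without preleukemic replicate 2 (0.0693) or leukemic replicate 3 (0.0642) or with the array medians set equal (0.05) and the oxidative phosphorylation call without preleukemic replicate 3 (0.0569) or leukemic replicate 1 (0.0571) or with the mean of all probe sets (0.0661). The stromal call ended without preleukemic replicate 1 or 3 or leukemic replicate 1 or 2 (0.066, 0.0523, 0.0545 and 0.123) and with the mean of all probe sets (0.0683).

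The count of 361 rested on single arrays. It was 1873 without preleukemic replicate 3, 8 without preleukemic replicate 1, 4 without preleukemic replicate 2, 53 without leukemic replicate 2 and 57 without leukemic replicate 3. It was 6 in a fit to these 2 groups alone, 3 with Xist as a covariate and 3819 with array weights. The share of calls that were higher was 40.2%, and 48.6% with the array medians set equal. That share was 51.6% without preleukemic replicate 3, 53.1% with array weights and 38% with cyclic loess, so the excess of falls depended on the setting. Of 48 called genes named by rule for this comparison, 1, Lrig3, stayed called under all 18 alternatives.

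The comparison of nilotinib with untreated leukemic mice asked what the drug changed in overt disease. After 7 days of nilotinib, 688 genes were higher and 413 lower. Among inhibitors of ERK signaling, Spry4 fell from 7.61 ± 0.67 to 4.06 ± 0.23 (SD, n = 3 each; SE 0.62, adjusted p = 0.00768) and Spry2 fell 1.98-fold (SE 0.16). Kit rose from 2.95 ± 0.15, near the floor, to 7.81 ± 0.23, and H2-Aa rose 24.6-fold (SE 0.77). Macrophage genes rose further than most, with C1qc up 65.5-fold (SE 0.56) and Adgre1, the macrophage antigen F4/80, 49.3-fold (SE 0.58). Tead1 fell 17.2-fold (SE 0.77), and Bche, butyrylcholinesterase, fell from 7.13 ± 0.48 to 2.77 ± 0.15, near the floor.

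Monocyte and macrophage markers rose in 16 of 19 members (18 when adjusted over the list alone), with a median log2 change of 5.16 (adjusted p = 1.6e-27, and adjusted p = 0.0722 with an estimated correlation). Fabp4 rose from 3.31 ± 0.41, near the floor, to 10.40 ± 1.13. Granulocyte markers rose in 3 of 17 members and in 16 when adjusted over the list alone (median 3.47, adjusted p = 4.8e-12, and adjusted p = 0.191 with an estimated correlation), including Lyz2, lysozyme, 22.2-fold (SE 0.66). Erythroid markers rose in 4 of 13 members (Slc4a1, the band 3 anion exchanger, 15.3-fold), T and NK cell markers in 6 of 23 with 1 lower (Thy1 13.9-fold), and plasma cell markers in 6 of 13 (Tnfrsf17, the receptor BCMA, 14.2-fold). When adjusted over the list alone, 10, 8 and 7 were higher, and 1, 1 and 0 lower. Stem and progenitor cell markers rose in 3 of 16 members, megakaryocyte and platelet markers in 1 of 13 and stromal and endothelial markers in 4 of 19, and adjusted over the list alone 6, 2 and 5 were higher, with 1 stromal gene lower. These 6 lists had adjusted p = 2.3e-07, 3.9e-07, 9.9e-07, 1.6e-05, 2.5e-04 and 3.2e-05. They had adjusted p = 0.146, 0.0722, 0.146, 0.108, 0.226 and 0.146 with an estimated correlation.

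**Figure D3:**
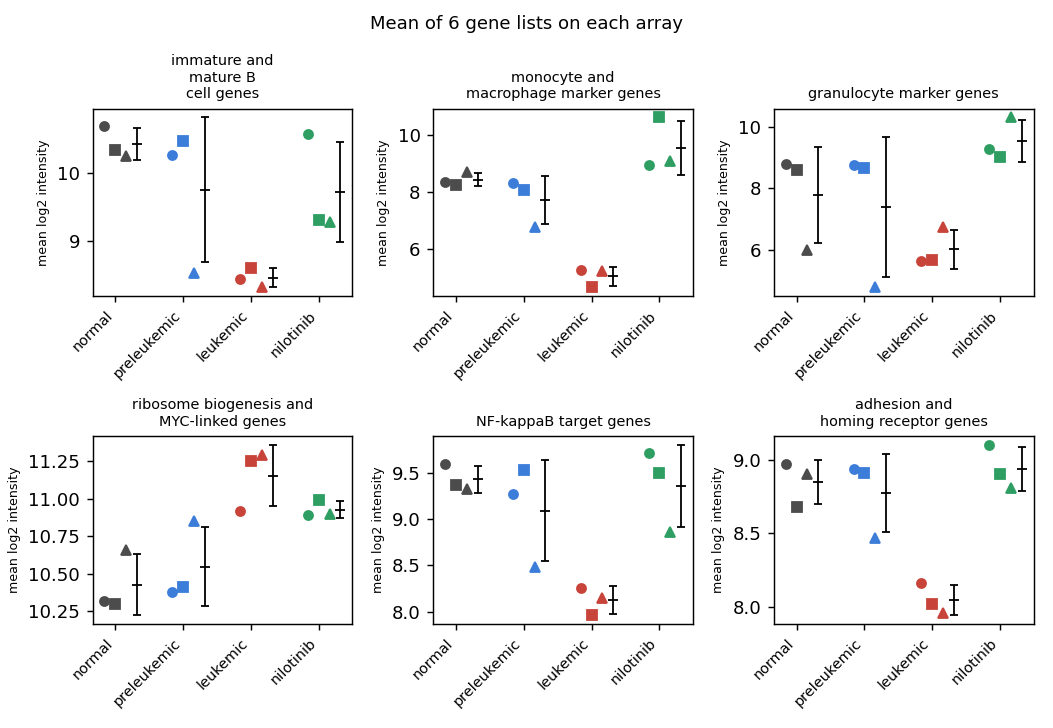
Mean log2 intensity of the measured members of 6 gene lists on each of the 12 arrays, by group. Circles, squares and triangles are replicates 1, 2 and 3, and black marks give the mean and SD of 3 mice. Macrophage markers lie between 4.66 and 5.26 in leukemic arrays and between 8.93 and 10.61 in nilotinib arrays.

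Several gene groups were called higher as lists alongside these markers, though most of their members did not pass. Immature and mature B cell genes rose in 4 of 31 members (7 when adjusted over the list alone), and the mean per array was 8.32 to 8.60 in leukemic arrays and 10.57, 9.31 and 9.27 in nilotinib arrays. The list was called (adjusted p = 6.5e-05, and adjusted p = 0.542 with an estimated correlation), but not without nilotinib replicate 1 (adjusted p = 0.102). NF-kappaB targets rose in 5 of 23 members (the same number adjusted over the list alone), including Ebi3, a cytokine subunit, 16.1-fold (SE 0.51), with adjusted p = 2.2e-07 and adjusted p = 0.191 with an estimated correlation. Immediate early genes rose in 2 of 26 (4 when adjusted over the list alone) and adhesion and homing receptor genes in 6 of 26 (9), Cd9 by 18.3-fold (SE 0.47) and Vcam1 by 58.8-fold (SE 0.89). Their adjusted p was 2.2e-07 and 5.8e-07, with adjusted p = 0.281 and 0.0722 with an estimated correlation. The mean of the immediate early genes was 9.91, 10.71 and 8.89 in nilotinib arrays and 8.87, 8.76 and 8.73 in leukemic arrays. Nilotinib replicate 3 thus lay near the leukemic arrays, and fry did not call that list (adjusted p = 0.0957). Sialylation and galectin genes rose in 4 of 29 members (6 higher and 2 lower when adjusted over the list alone). Lgals3, a galectin of macrophages, rose 20.9-fold (SE 0.55). The list had adjusted p = 0.0152 and adjusted p = 0.215 with an estimated correlation, and its call ended without leukemic replicate 3 (adjusted p = 0.0836) or nilotinib replicate 1 (0.131). Beside all of these groups, the mean of the macrophage markers lay between 4.66 and 5.26 in leukemic arrays and between 8.93 and 10.61 in nilotinib arrays.

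Pro-B and pre-B cell genes rose in 3 of 25 members (5 higher and 1 lower when adjusted over the list alone), among them Kit (median 0.14, adjusted p = 0.00169, and adjusted p = 0.191 with an estimated correlation). B-lineage transcription factors rose in 2 of 31 members and the list did not pass (adjusted p = 0.0774). Ikzf2, the transcription factor Helios, rose 4.81-fold (SE 0.33). MAPK and ERK feedback genes fell in 4 of 23 members and rose in 5, and the list did not pass (median -0.35, mean 0.07, direction up, adjusted p = 0.806). The rises held Plaur, the urokinase receptor, 4.54-fold (SE 0.30) and Emp1 5.81-fold (SE 0.43). Adjusted over the list alone, 6 were higher and 5 lower. Of 19 STAT5 targets, 1 was called, Lrp1, a receptor also found on macrophages, up 10.7-fold (SE 0.56), and the list did not pass (median -0.13, mean 0.12, direction up, adjusted p = 0.731). Ribosome biogenesis and MYC-linked genes had 0 of 33 members called, over all genes or adjusted over the list alone, and a median of -0.18 (adjusted p = 0.0116, and adjusted p = 0.707 with an estimated correlation). The call of that list ended without leukemic replicate 3 (adjusted p = 0.163) or nilotinib replicate 3 (0.0552).

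Of 25 p53 targets, 3 fell and 1 rose (8 and 1 when adjusted over the list alone; median -0.33, adjusted p = 0.045, and adjusted p = 0.512 with an estimated correlation). The p53 list ended with the array medians set equal (adjusted p = 0.137), the dim-probe filter (0.0925), the mean of all probe sets (0.0939), or without leukemic replicate 1 (0.0676), leukemic replicate 3 (0.126) or nilotinib replicate 3 (0.282). FoxO targets (median -0.05, mean 0.14, direction up, adjusted p = 0.352), glycolysis genes (median -0.10, mean 0.12, direction up, 0.806), unfolded protein and ATF4 response genes (median -0.03, mean 0.12, direction up, 0.806) and interferon response genes (median 0.08, mean 0.50, 0.0565) did not pass. Pfkfb4, a regulator of glycolysis, rose 3.53-fold (SE 0.22), and Ifitm3, an antiviral membrane protein, 18.6-fold (SE 0.67). Also not passing were the S phase (adjusted p = 0.598), G2 and mitosis (0.518), oxidative phosphorylation (0.518), cholesterol biosynthesis (0.283), BCL2 family (0.518) and sex-linked (median -0.23, mean 0.05, direction up, 0.915) lists.

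The arrays of the groups did not overlap in 1099 of the 1101 called genes, and in 26.1% of all genes, where chance gives 10%. The share of calls that were higher was 62.5%, and 47.7% with the array medians set equal, which moved the median change of all genes from -0.052 to -0.156. The count of calls was 632 without leukemic replicate 3 and 632 without nilotinib replicate 2. Of 86 called genes named by rule, 48 stayed called under all 19 alternatives.

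The comparison of nilotinib with normal cells asked what still differed from wild type after treatment. Nilotinib cells had 736 genes higher and 1119 lower. Rbm24 remained low, at 4.98 ± 0.70 against 10.27 ± 0.23 (SD, n = 3 each; SE 0.90, adjusted p = 0.0129), and Bach2 was 2.00-fold lower (SE 0.17). Socs2 was 3.46-fold higher (SE 0.36) and Cish 5.65-fold higher (SE 0.53), calls that ended in 3 and 4 of the 19 alternatives, while the other genes of this paragraph stayed called in all. Slc2a3 was 2.35-fold (SE 0.23) and Fdps, an enzyme of the mevalonate pathway, 3.60-fold higher (SE 0.30), while Gne, which starts sialic acid synthesis, was 2.66-fold lower (SE 0.21).

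Ribosome biogenesis and MYC-linked genes were higher in 8 of 33 members (17 when adjusted over the list alone), cholesterol biosynthesis genes in 7 of 20 (9, and 1 lower), glycolysis genes in 5 of 23 (8, and 2 lower) and S phase genes in 1 of 36 (1). The 4 lists had adjusted p = 4.2e-09, 1.1e-04, 8.7e-04 and 3.5e-04, and adjusted p = 0.641, 0.436, 0.436 and 0.659 with an estimated correlation. Unfolded protein and ATF4 response genes (1 of 34 higher, also when adjusted over the list alone; median 0.34) and oxidative phosphorylation genes (1 of 37 higher, 0 when adjusted over the list alone; median 0.14) had adjusted p = 2.8e-04 and 6.8e-04. With an estimated correlation they had adjusted p = 0.646 and 0.659. FoxO targets were lower in 4 and higher in 1 of 24 members (5 and 1 when adjusted over the list alone; adjusted p = 0.00136, and adjusted p = 0.436 with an estimated correlation). Immature and mature B cell genes were lower in 4 of 31, also when adjusted over the list alone (adjusted p = 0.00945, and adjusted p = 0.722 with an estimated correlation). Pro-B and pre-B cell genes were higher in 6 and lower in 2 of 25 members and the list did not pass (median -0.05, mean 0.28, direction up, adjusted p = 0.382). Of the STAT5 targets, 5 were higher and 2 lower, and the list did not pass (adjusted p = 0.381). Sialylation and galectin genes were lower in 6 and higher in 2 of 29 (adjusted p = 0.765), with Siglecg, an inhibitory receptor of B cells, 2.63-fold lower (SE 0.21). B-lineage transcription factors (adjusted p = 0.192), MAPK and ERK feedback genes (0.101), G2 and mitosis genes (0.152), interferon response genes (0.661), p53 targets (0.659), BCL2 family genes (median -0.06, mean 0.16, direction up, 0.829), NF-kappaB targets (0.661), immediate early genes (0.598) and adhesion genes (0.633) did not pass as lists.

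Monocyte and macrophage markers were higher than normal in 5 of 19 members (7 when adjusted over the list alone), granulocyte markers in 1 of 17 (1) and T and NK cell markers in 2 of 23 with 1 lower (4 and 1), among them Thy1 6.32-fold higher (SE 0.41). Their adjusted p was 3.1e-04, 3.1e-04 and 9.9e-04, with adjusted p = 0.646, 0.646 and 0.436 with an estimated correlation. Erythroid (1 of 13 higher) and plasma cell markers (3 of 13 higher) had adjusted p = 0.0376 and 0.0471, and adjusted p = 0.646 and 0.646 with an estimated correlation. The erythroid call ended without normal replicate 2 or 3 or nilotinib replicate 2 or 3 (adjusted p = 0.0952, 0.11, 0.126 and 0.191) and with the filter on dim probe sets (0.237). The plasma cell call ended without normal replicate 1 or 2 or nilotinib replicate 1 or 2 (adjusted p = 0.0503, 0.153, 0.307 and 0.0733), with the filter (0.155) and with the mean of all probe sets (0.0715).

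Of 87 called genes named by rule for this comparison, 14 stayed called under all 19 alternatives, and 72 calls ended without nilotinib replicate 2. The count of 1855 was 359 without nilotinib replicate 2, 625 without nilotinib replicate 3, 1216 without nilotinib replicate 1, 640 without normal replicate 1, 701 without normal replicate 2 and 1201 with Xist as a covariate. The share of calls that were higher was 39.7%, 27.5% with the array medians set equal and 49.8% with cyclic loess. Without 1 array the calls of other lists ended as well, at adjusted p = 0.0803 (normal replicate 1) and 0.191 (nilotinib replicate 3) for immature and mature B cell genes, 0.0567 (normal replicate 1) for S phase genes and 0.116 (normal replicate 2) for oxidative phosphorylation genes. For FoxO targets the mean of all probe sets gave 0.102.

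Many genes differed in opposite directions in 2 comparisons, leukemic with normal and nilotinib with leukemic. The macrophage markers went this way too, with list medians of -3.78 and 5.16. A changed share of other cells in the sort was not separated here from changes within B-lineage cells. Of the 3204 genes called between leukemic and normal cells, 623 were called in the opposite direction between nilotinib and leukemic cells. Among these, 368 were lower in leukemic and then higher with nilotinib, where independent lists would share 61.3, and 255 were higher and then lower, where independent lists would share 35.9. A single gene, Foxred2, was called in the same direction (0.59 and 0.76 on the log2 scale). Of the 623 genes, 5 were still called against normal after nilotinib in the same direction as in leukemia. Calls against normal in the opposite direction were not counted among the 623, so the rest are not all at the normal level. Of the 3204 genes, 1057 were called in the same direction between nilotinib and normal cells and 44 in the opposite direction. The 2 comparisons share the 3 leukemic arrays, which by itself gives opposite signs. The covariance of all changes was -0.455, and -0.039 in 20 simulations of unchanged groups with shared arrays (r of -0.71 and -0.50). The count of 623 was 320 without leukemic replicate 3 and 386 without nilotinib replicate 2.

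A comparison with no shared array set the change from normal to preleukemic beside that from leukemic to nilotinib. Across the 18193 genes, Pearson's r was -0.41 and Spearman's rho -0.22, with a covariance of -0.1186 against 1e-04 in simulated unchanged groups. Genes are not independent replicates, so no p is given. Without preleukemic replicate 3 the correlation was -0.16. Since 0 genes were called in limma between preleukemic and normal cells, their overlap with leukemic calls was 0, and the shift of such genes under nilotinib could not be tested. Over the 4 groups at once, the F test called 2695 genes, and 1289 without leukemic replicate 3, 1497 without normal replicate 1, 1551 without nilotinib replicate 2, 1764 without preleukemic replicate 1, 1769 without nilotinib replicate 3, 791 with Xist as a covariate and 4499 with array weights.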

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

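The tests of macrophage share, scaling of the macrophage markers, and degradation and label swap in preleukemic replicate 3 were chosen after the result was seen, as were the restriction to markers above the floor and the reference arrays left out in turn. The sizes of change with Xist as a covariate were likewise not a measure set beforehand. Between preleukemic and leukemic mice, 361 genes differed in their distance from normal, since both are set against the same normal arrays, and the moderated test of the difference itself called them. Probe sets outside the gene table, which name no gene or several, also carried signal. Of 10092 such probe sets, 766 were called between leukemic and normal cells (374 higher, 392 lower) and 326 between nilotinib and leukemic cells (224 higher, 102 lower).

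Macrophage markers were low in leukemic arrays and high in nilotinib arrays. The median change of all genes from leukemic to nilotinib was -0.052, while the median of the macrophage list was 5.16. Normalization between arrays by RMA holds the first value near 0, so this test cannot decide on scaling before that step. It shows only that no uniform shift of the size of 5.16 remained in the deposited values. A general fall in sort purity stays open, as the 68 markers of T and NK, erythroid, megakaryocyte and stromal cells had a median change of 0.58, but 10 of them had a normal mean of at least 7, too few to decide. Among markers with such a normal mean, the median change was 5.27 for 16 macrophage, 3.80 for 10 granulocyte, 1.11 for 10 plasma cell, 3.13 for 3 erythroid, 3.09 for 3 megakaryocyte, 0.17 for 3 T and NK and 0.05 for 4 stem cell genes, and 5.88 for 1 stromal gene. A different share of macrophage-lineage cells or of their RNA, despite the CD19 and AA4.1 gate, stays open beside a change of these genes within B-lineage cells, since all 16 macrophage genes (100%) lay over 1 log2 unit higher with nilotinib and both would give this.

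Preleukemic replicate 3 lay near the leukemic arrays, at a position of 0.70. Degraded RNA is argued against by its Gapdh 3' to 5' difference of 0.83, within the range of the other arrays. A swap with a leukemic array is argued against, because the lowest position of a leukemic array was 0.80. A mixture of leukemic cells and cells like those of the other preleukemic mice stays open. The leukemic share was 0.64 from 633 genes higher and 0.78 from 671 genes lower in leukemic cells, a difference of 0.15 (0.13 to 0.18 with 1 reference array left out), while the granulocyte mean of 4.79 lay below the 5.65 to 8.77 of the reference arrays, which a mixture of whole samples would not give, though these markers also varied among normal mice; an earlier course of the disease in that mouse and a wrong label from outside the series were not tested.

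Genes called between leukemic and normal cells were weighed against 3 technical causes. With Xist as a covariate, the calls fell from 3204 to 886, below the bound that had been set beforehand as a sign of sex. Of the 3204 calls, 96% kept their direction at an unadjusted p under 0.05, which had been set as a sign against it. For leukemic with preleukemic that share was 100% although 0.8% stayed called, so it cannot decide the question. The median change of the 3204 genes was 1.03 without and 0.96 with the covariate, and their median SE 0.23 and 0.28. The calls thus ended mainly through wider errors. The kept size of the change argues against sex as the whole cause for these genes, and sex stays open as a part. This measure was not set beforehand and was read on genes selected in the main fit, so it is the weaker for it. Degraded RNA in normal replicate 2 is argued against as the whole cause, since 59.4% of the calls remained without that array, although the count fell to 2094. With the array medians set equal, 91.9% remained, and age, which differs between groups by design or is not given, stays open as untested.

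For groups of 3 the 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 0 calls for preleukemic with normal (highest other 1, so that all 10 splits gave as many), 3204 for leukemic with normal (highest other 1), 361 for leukemic with preleukemic (highest other 72, with preleukemic replicates 1 and 2 and leukemic replicate 2 set against the rest), 1101 for nilotinib with leukemic (highest other 1) and 1855 for nilotinib with normal (highest other 0). In each of the last 4 comparisons 1 split, the real one, gave as many. For the F test, 1 of 100 drawn splits of the 12 arrays, the real one with 2695, gave as many calls, and the highest other gave 96. This argues against chance there as far as 100 splits can show. It does not bear on sex, age or cell share, which may differ between the groups.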

How the results depend on the processing

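Leaving out both preleukemic replicate 3 and normal replicate 2, or preleukemic replicate 3 where it is in neither group, was chosen after the arrays were seen. Of 6458 values of named genes under alternatives, 5425 stayed on their side of the threshold. A further 1027 kept direction but no longer passed, and 6 newly passed (Bcr, leukemic with preleukemic). Direction was compared only where a value passed in the main fit or in the alternative, and 0 of these reversed. Of 1050 list values, 840 stayed, 208 no longer passed and 2 reversed, and of 237 counts and main values, 188 stayed and 49 moved. Background values were not used here, so genes near the floor could not be told from undetected ones.

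With Xist as a covariate, 886 genes were called for leukemic with normal, 3 for leukemic with preleukemic, 1201 for nilotinib with normal and 791 in the F test. With array weights, which were 0.271 for normal replicate 2 and 0.491 for preleukemic replicate 3, 3819 were called for leukemic with preleukemic and 4499 in the F test. With every probe set tested by itself, 45037 in place of 18193 tests, the counts were 5600 for leukemic with normal, 1883 for nilotinib with leukemic, 2844 for nilotinib with normal and 4287 in the F test. In a fit to the groups of the comparison alone, 6 genes were called for leukemic with preleukemic. Leaving out both arrays gave 2310 there, and 2987, 1529, 1658 and 0 for leukemic with normal, nilotinib with leukemic, nilotinib with normal and preleukemic with normal. Apart from the change sizes and errors given above for leukemic with normal under Xist, the cause was not tested for any of these.

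Gene lists called numbered 0 in each comparison with an estimated correlation, and with fry 0 for preleukemic with normal, 10 for leukemic with normal, 10 for leukemic with preleukemic, 11 for nilotinib with leukemic and 4 for nilotinib with normal. The mean of all probe sets gave 12 lists for preleukemic with normal. For preleukemic with normal, the camera adjusted p of immature and mature B cell genes ranged from 4.9e-06 without preleukemic replicate 2 to 0.991 without both arrays. Without preleukemic replicate 3 the direction of that list relative to all other genes reversed (0.795). The adjusted p of ribosome biogenesis genes ranged from 2.2e-05 without normal replicate 3 to 0.923 with an estimated correlation. It was 0.789 without preleukemic replicate 3, and the direction relative to all other genes reversed without both arrays (0.284). The cause was not tested.

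With 1 array left out, which leaves 2 in its group with the pooled spread, calls ranged from 0 to 0 for preleukemic with normal, 1642 to 3534 for leukemic with normal, 4 to 1873 for leukemic with preleukemic, 632 to 1376 for nilotinib with leukemic, 359 to 2458 for nilotinib with normal and 1289 to 3442 in the F test. The highest were reached without preleukemic replicate 3. Lists called ranged from 2 (without normal replicate 1; 3 without normal replicate 2) to 9, 17 to 21, 19 to 23, 13 to 16 and 10 to 14 in the same order. The correlation of changes ranged from -0.47 to -0.16 and was -0.32 without normal replicate 3, the overlap was 0, and opposite calls ranged from 320 to 883.

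The replicate numbers as a block gave 588 genes for leukemic with preleukemic, 3366 for leukemic with normal, 1032 for nilotinib with leukemic, 2098 for nilotinib with normal, 0 for preleukemic with normal and 2737 in the F test. With the block, the camera call of MAPK and ERK feedback genes ended for preleukemic with normal (adjusted p = 0.073). That of p53 targets ended for nilotinib with leukemic (adjusted p = 0.0538). The 18 pairs of arrays with the same number had residual correlations from -0.09 to 0.28, 5 of them over 0.1, and 5 of 12 arrays correlated best with an array of their number, so the numbers were not read as pairs. Array medians set equal moved the median change of all genes from -0.055 to -0.105 for preleukemic with normal, 0.039 to 0.108 for leukemic with preleukemic, -0.052 to -0.156 for nilotinib with leukemic and -0.046 to -0.132 for nilotinib with normal. The shift under nilotinib of genes changed in preleukemic mice had no value under any setting, since 0 genes were called.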

Other observations

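Of the Y-linked genes, Kdm5d and Uty were high in the same 3 arrays, and Eif2s3y departed from them in 1. Kdm5d read 8.01, 7.76 and 7.98 in leukemic replicates 2 and 3 and nilotinib replicate 3 with 1 of its 3 probe sets, and 2.28 or less elsewhere. A second probe set of Kdm5d read 5.31, 4.70 and 6.02 in these arrays and 3.86 or less elsewhere, and Uty read 6.77, 6.05 and 6.46 and 2.33 or less elsewhere with 1 of its 4 probe sets. Eif2s3y read 11.27 in leukemic replicate 3 and 11.29 in nilotinib replicate 3, but 5.57 in leukemic replicate 2, and 3.07 or less elsewhere. These are the arrays in which Xist was 5.43, 4.89 and 4.17. Kdm5d, Uty and Eif2s3y were singled out after their values were seen.

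Values of 3 genes picked after they were seen are given here without a test. For Iglv1 and Ighg3 the reason is that immunoglobulin sequences are shared or clonal. Jchain is not such a sequence and is a member of the plasma cell marker list tested above. Iglv1, a lambda light chain segment, was 12.25 ± 0.43 in normal and 6.63 ± 0.58 in leukemic cells (SD, n = 3 each), 10.83 ± 2.62 in preleukemic and 12.31 ± 0.73 in nilotinib cells. Ighg3, a heavy chain constant gene of switched B cells, was 6.05 ± 1.45 in normal, 6.67 ± 2.17 in preleukemic, 4.47 ± 0.12 in leukemic and 10.74 ± 1.93 in nilotinib cells. Jchain, the joining chain of secreted immunoglobulin, was 12.26 ± 0.22 in normal, 10.75 ± 2.55 in preleukemic, 8.56 ± 0.35 in leukemic and 13.25 ± 0.45 in nilotinib cells. Preleukemic replicates 1 and 2 were the closest pair of arrays, with r = 0.9960 across probe sets, against a lowest r of 0.9791 within a group.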
